A study of Macaca mulatta with 20 samples.

How the data were processed

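The series holds 20 two-colour arrays of oropharyngeal (buccal) mucosa of rhesus macaques (Macaca mulatta). Per the labels, each array carried 825 ng of amplified cDNA of 1 infected animal in Cy5 and 825 ng of a pool of uninfected animals in Cy3, and the dyes were not swapped on any array. Arrays were grouped by the infection the labels give: LCV (4), SIV (4) and both viruses (12). Replicate numbers pair nothing, so no paired test was made.

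The deposited values were read as log10 ratios of Cy5 over Cy3. As deposited, the median of each array over all features was 0, and how this came about is not given in the sources used here. The log base was inferred from the values, since the labels do not give it, and the direction was taken from the dyes in the labels. The base rests on values written to as many as 10 significant digits, on many exact zeros and on 6 sets of replicated features that span 1.77 log10 units. Scanner, image extraction, background correction, normalization and amplification method are not given in the sources used here, nor is the number of animals in the pool. If the base were another one, each log2 change would scale by 1 common factor, with its direction and p unchanged.

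The deposited table had 45220 features, of which 3369 were blank on every array. An exact 0 was read as not measured, which applied to between 12.4% and 19.7% of features per array and left 33602 to 36642 measured features. The reading of 0, and with it the centring on measured features only, was decided once the values had been seen. Values were converted to log2 and each array was centred on the median of its measured features, which moved arrays by between -0.01 and 0.14. The platform table named 5412 features, and 36439 features with values had no name and were not tested as genes. Symbols were brought up to date through accessions, gene IDs and synonyms where these were unambiguous, and 12 symbols with conflicting evidence are not named. The measured features of a gene were averaged per array. A gene was tested if measured on at least 3 LCV, 3 SIV and 9 co-infection arrays, which left 2198 genes. Features of the same gene had a median lowest correlation of 0.944, but it was under 0.5 for 327 genes, including the named genes HSD17B3 (0.135), INHBA (0.0588), KRIT1 (0.212), KNTC1 (0.366), CDC6 (0.481), IFNG (0.227), TRAF1 (0.197), CLCA1 (0.336) and TICAM2 (-0.352), and CCL3, where 2 of 4 features were measured on few arrays.

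Groups were compared in 1 fit of group means over all 20 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests, Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. The 3 comparisons against the pool test a group mean against 0, so they leave out the spread between uninfected animals and cannot remove a fixed dye effect. In the 3 comparisons between infected groups, pool and dye cancel. The ± values beside log2 changes are the moderated standard errors of the fit, and those beside means of gene lists are standard deviations over arrays. The fit shares 1 spread per gene among the 3 groups, so its errors are too small for a group that varies more than the others.

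Of 37 gene lists (pathways and markers of cell types that oral mucosa can hold), 15 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. The adjustment was over the lists of a comparison, and the tests were repeated with an estimated correlation and with fry, which tests whether a list's genes move 1 way without comparing them with other genes. Camera called 22 of 90 tests with the preset correlation and 0 with an estimated one (smallest adjusted p 0.414), and fry called 26. Missing values (0.541% of cells) were set to the group mean for these tests only. The genes named in the text followed a rule: per comparison the 8 largest rises and the 8 largest falls among called genes with an ordinary symbol (against the pool only those with 1 sign on every array), up to 3 members of each called list, and the called member with the smallest p of each other list. Where no gene was called, 5 genes per direction are given as not passing. The groups, comparisons, tests, lists, naming rule and alternative settings, other than those marked as added later, were fixed before the data were examined.

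Lists of skeletal muscle, salivary gland and stratified epithelium genes were added after the data had been seen, since the fixed muscle list had 1 measured gene, and they hold genes already seen to move. Their means per array were taken over the members measured on every array and compared between groups with exact two-sided permutation tests. Relations within the 12 co-infection arrays used permutation tests with 1e+05 resamples.

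The fit was tested on simulated data with 200 changed genes among 2198. It recovered 68% of LCV, 63% of SIV and 88% of co-infection changes of 1 (log2) against the pool, and 29% between SIV and LCV, 58% between co-infection and LCV and 61% between co-infection and SIV. Between 1.85% and 5.62% of the calls were false, and camera called 0 lists in unchanged simulated data, in which genes vary independently.

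The alternatives were no centring, arrays on 1 scale, quantile normalization, genes measured on all 20 arrays, genes measured on at least 2 arrays of each group, every feature on its own, array quality weights, a robust fit, only the arrays of the groups compared, and leaving out each array in turn. After the data had been seen, 3 were added: exact zeros kept as ratios, the muscle mean as a covariate, and centring on the replicated features. Other splits of the arrays into groups of the same sizes were fitted in the same way (35 for SIV against LCV, 100 drawn at random for each of the others). The overlap of the responses to the pool was set beside 100 simulations of unchanged groups that share 1 pool. No array was left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for preparation, scores and figures.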

Results

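Gene expression was measured in oropharyngeal (buccal) mucosa of rhesus macaques on 20 two-colour microarrays. Each array set amplified cDNA of 1 infected animal, labelled with Cy5, against a pool of uninfected animals, labelled with Cy3, and each array held a different named animal. The infected animals carried lymphocryptovirus (LCV, a herpesvirus of B cells related to Epstein-Barr virus; 4 arrays), simian immunodeficiency virus (SIV; 4 arrays) or both viruses (12 arrays). Values are log2 ratios of the infected animal to the pool, so a value of 0 is the level of the pool. Between 33602 and 36642 features were measured per array, and 2198 named genes were tested. The number of arrays limits the precision, and the pool stands for a single control sample whose own spread is not known. The labels name a study of SIV and LCV co-infection, so the comparisons ask how the mucosa of each infected group differed from uninfected mucosa and how the groups differed from each other.

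In the 4 LCV animals, some genes of cell division were higher than in the uninfected pool, while most measured genes of connective tissue and skeletal muscle and some of gland secretion were lower. MCM3 and MCM5, subunits of the helicase that unwinds DNA for replication, rose by 1.19 ± 0.33 and 1.15 ± 0.27 (log2 ratio ± SE, n = 4). CKAP2, a protein of the mitotic spindle, rose by 1.83 ± 0.36, and the kinetochore genes CENPK and KNTC1 rose by 2.07 ± 0.50 and 1.66 ± 0.38. BGN, which encodes the matrix proteoglycan biglycan, fell by 1.77 ± 0.19 and was below the pool on 4 of 4 arrays (limma adjusted p = 9.86e-06). LACRT, a secreted gland protein, fell by 4.58 ± 0.62, and NRAP, an anchoring protein of muscle fibres, fell by 4.09 ± 0.84.

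Of the 7 measured cell cycle and proliferation genes, 3 rose in LCV, among them CDC6 (0.63 ± 0.18), a loader of the replicative helicase, and 4 did not pass, while 7 rose when adjusted over the list alone. The list median was 0.99 and its camera adjusted p was 0.000316, but the adjusted p = 0.444 with an estimated correlation. Of the 8 fibroblast and extracellular matrix genes, 5 fell and 3 did not pass (6 fell when adjusted over the list alone), with PDGFRA, a growth factor receptor of fibroblasts, at -1.53 ± 0.35 and the protease gene CTSK at -1.43 ± 0.39. That list had a median of -1.23 and an adjusted p of 0.000316 (adjusted p = 0.444 with an estimated correlation). Of the 9 interferon-stimulated genes, 3 fell and 6 did not pass (5 fell when adjusted over the list alone), namely OAS1 (-2.34 ± 0.56), IFI27 (-3.05 ± 0.77) and IFIT3 (-2.28 ± 0.72). Their list median was -1.54 with an adjusted p of 0.0349 (adjusted p = 0.584 with an estimated correlation). The mean of these 9 genes was 0.03 on LCV replicate 2 and between -1.97 and -1.67 on the other LCV arrays. In smaller or uncalled lists, the lymphatic endothelial receptor LYVE1 fell by 2.53 ± 0.59, the antiretroviral deaminase APOBEC3G fell by 2.28 ± 0.52, the antimicrobial peptide gene CAMP fell by 2.93 ± 0.60 and the growth factor EGF fell by 2.96 ± 0.65.

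Muscle genes were low on every LCV array. The mean of a muscle gene list written after the data had been seen was -1.95 ± 0.62 (SD, n = 4), and of its 20 measured genes 13 fell and 1 rose. Of the 8 measured genes of a gland list written in the same way, 3 fell and 1 rose. The mean of the gland list was alike in LCV (-2.02), SIV (-2.16) and co-infection (-2.02), so it may belong to the pool. The mean of a list of stratified epithelium genes, also written after the data had been seen, was -0.01 ± 0.11 on these arrays. With the muscle mean as a covariate, which sets each group at the pool's level of muscle genes, the medians in LCV were 0.29 for the cell cycle list, -0.80 for the matrix list and -0.75 for the interferon list. MCM3 was then at 0.39 ± 0.29, MCM5 at 0.54 ± 0.26, CDC6 at 0.29 ± 0.20, CENPK at 1.09 ± 0.53 and KNTC1 at 1.004 ± 0.44, with adjusted p values of 0.403, 0.185, 0.343, 0.187 and 0.143. OAS1, IFI27, IFIT3, PDGFRA, CTSK and LYVE1 (-1.16 ± 0.56) did not pass either. CKAP2 (1.50 ± 0.46), BGN (-1.87 ± 0.24), LACRT (-4.60 ± 0.80), APOBEC3G (-2.28 ± 0.67) and CAMP (-4.09 ± 0.63) passed. EGF (-0.80 ± 0.21) and NRAP (-1.30 ± 0.29) also passed, with smaller falls than without the covariate. NRAP is a member of the muscle list, so its smaller fall is built into that fit. The tests against the pool carry the pool's own error and any fixed dye effect.

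By limma, 309 of the 2198 genes were called in LCV against the pool at an adjusted p under 0.05, with 138 higher and 171 lower. Without centring of the arrays the split was 192 higher and 141 lower. The count was 143 without LCV replicate 1, 111 without replicate 2, 109 without replicate 3 and 134 without replicate 4, and 72 genes were called in the same direction whichever 1 array was left out. It was 597 with arrays on 1 scale, 542 after quantile normalization, 984 with array weights and 839 when the spread was taken from the LCV arrays alone. Those 72 included CYP2F1, CKAP2, KNTC1, NEIL3, LACRT, NRAP, SLCO1A2, MAP1A, APOBEC3G, CAMP, BGN and SFRP4, and no other gene named by the rule for this comparison.

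**Figure D1:**
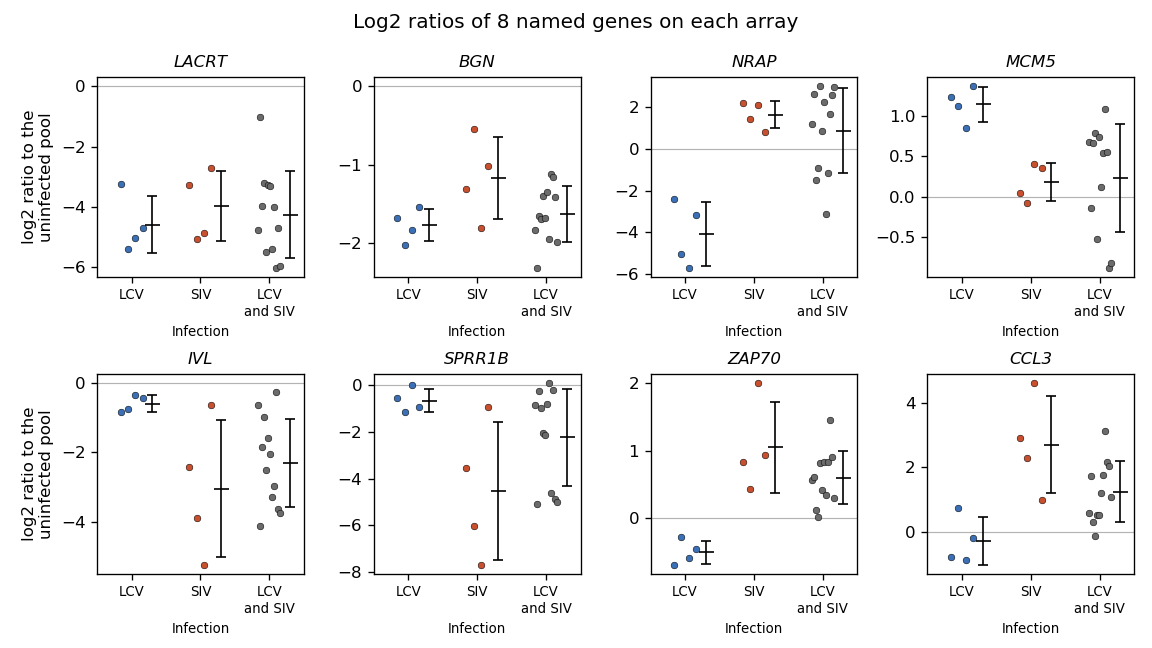
Log2 ratios to the uninfected pool of 8 genes chosen from those named in the text (y axis, 1 scale per gene), by infection (x axis). Each point is 1 array (4 LCV, 4 SIV, 12 LCV and SIV), and the bars give the mean and SD of the group; LACRT and BGN lie below 0 on every array.

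On average over the 4 SIV animals, genes of the differentiated surface epithelium were far lower than in the pool. The animals differed widely, with a mean of the late epithelial list of -6.95 on SIV replicate 3 and -0.51 on SIV replicate 4. Some genes of lymphocytes and of the respiratory chain were higher. SPRR1B and IVL, which encode proteins of the cornified envelope, fell by 4.55 ± 0.98 and 3.05 ± 0.63 (n = 4), and the desmosomal cadherin DSG3 fell by 3.23 ± 0.88. CCL3, a chemokine that draws leukocytes, rose by 2.70 ± 0.49 and was higher on 4 of 4 arrays (limma adjusted p = 0.0014). MS4A1, which encodes the B cell antigen CD20, rose by 2.33 ± 0.54 (n = 3), and ITGA4, an integrin subunit of leukocytes, rose by 2.60 ± 0.72 (n = 3). SMR3A, a gene of salivary secretion, fell by 7.85 ± 1.42, but it was below the pool on all 20 arrays, so part of this may belong to the pool.

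Of the 5 measured genes of the cornified envelope and late epithelial differentiation, 5 fell in SIV, both over all genes and adjusted over the list alone, with KLK10 at -4.17 ± 0.94 beside SPRR1B and IVL. The list median was -3.48 with a camera adjusted p of 0.00146 (adjusted p = 0.545 with an estimated correlation). Of the 7 T cell genes, 2 rose and 5 did not pass (3 rose when adjusted over the list alone). They were ZAP70, a kinase of T cell receptor signalling (1.05 ± 0.21), and CD3G, a chain of the receptor complex (2.01 ± 0.65), whereas IL7R was at 1.26 ± 0.48 with an adjusted p of 0.0589. The T cell list median was 1.22 with an adjusted p of 0.0238 (adjusted p = 0.545 with an estimated correlation). Of the 12 oxidative phosphorylation genes, 5 rose and 7 did not pass, and 10 rose when adjusted over the list alone, with UQCR11 at 1.02 ± 0.26 and NDUFC1 at 0.97 ± 0.29. That list median was 0.81 with an adjusted p of 0.00121 (adjusted p = 0.545 with an estimated correlation). Of the 6 lipid and steroid genes, 3 fell and 3 did not pass (6 fell when adjusted over the list alone), among them the sterol synthesis genes DHCR7 (-1.34 ± 0.37) and SC5D (-1.52 ± 0.50). Their median was -1.16 with an adjusted p of 0.0124 (adjusted p = 0.545 with an estimated correlation). Among lists too small to test, IFNG rose by 1.30 ± 0.33, MAMU-E rose by 0.9997 ± 0.29, and the neutrophil granule gene MPO fell by 1.90 ± 0.47.

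On the SIV arrays the mean of the muscle list was 1.35 ± 0.71 (SD, n = 4), with 2 of its 20 genes called higher, and the mean of the stratified epithelium list was -2.56 ± 2.12, with 13 of its 18 genes called lower. The epithelial mean ran from -5.24 to -0.37 across the 4 SIV arrays. With the muscle mean as a covariate, the medians in SIV were 0.24 for oxidative phosphorylation, -0.37 for lipid and steroid genes, -2.79 for late epithelial genes and 1.80 for T cell genes. UQCR11 was then at 0.48 ± 0.15, NDUFC1 at 0.41 ± 0.19, NDUFB10 at 0.40 ± 0.23, DHCR7 at -0.86 ± 0.36 and SC5D at -0.94 ± 0.50, with adjusted p values of 0.0783, 0.196, 0.312, 0.154 and 0.262. SPRR1B (-3.47 ± 1.01), KLK10 (-3.06 ± 0.95) and CD3G (2.38 ± 0.73) did not pass either (adjusted p 0.0533, 0.0675 and 0.0643). Nor did MS4A1 (2.19 ± 0.64), ITGA4 (2.50 ± 0.85), DSG3 (-2.54 ± 0.96) or MAMU-E (0.87 ± 0.33), with adjusted p values of 0.0600, 0.0927, 0.122 and 0.121. IVL (-2.67 ± 0.70), ZAP70 (0.88 ± 0.23), CCL3 (2.63 ± 0.57), SMR3A (-7.08 ± 1.61), IFNG (1.39 ± 0.38) and MPO (-1.92 ± 0.55) passed.

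In SIV against the pool limma called 494 genes, with 214 higher and 280 lower, and without centring the split was 307 higher and 235 lower. The count was 290 without SIV replicate 1, 138 without replicate 2, 91 without replicate 3 and 640 without replicate 4, and it was 37 when the spread was taken from the SIV arrays alone. The late epithelial mean had an SD of 2.82 over the SIV arrays, 1.59 over co-infection and 0.30 over LCV. For such genes the shared spread of the fit understates the error in SIV. The 69 genes called whichever 1 array was left out included CCL3, SMR3A, CRYGS, LACRT, SLCO1A2, DERL3, PI3, ODAM and BGN, but no other gene named by the rule for this comparison, so not ZAP70, CD3G, IVL or SPRR1B.

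In the 12 co-infected animals, 6 of the 8 gland genes and 8 of the 18 stratified epithelium genes were lower than in the pool and every measured gene of the respiratory chain list was higher. LACRT fell by 4.25 ± 0.36 and PIP, a secreted protein of salivary glands, fell by 2.78 ± 0.50 (n = 12). HSD17B3, an enzyme of testosterone synthesis, fell by 2.60 ± 0.14 and was below the pool on 12 of 12 arrays (limma adjusted p = 1.18e-10). LACRT, PIP and HSD17B3 were also below the pool on every LCV and SIV array, so their falls may belong to the pool. SLURP1, a secreted protein of keratinocytes, fell by 2.93 ± 0.30, and IVL fell by 2.30 ± 0.36. SEMA7A rose by 1.71 ± 0.30 (n = 10), ITGA4 rose by 1.70 ± 0.36 and LSM5, a component of RNA processing complexes, rose by 1.63 ± 0.21.

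Of the 12 oxidative phosphorylation genes, 12 rose in co-infection, both over all genes and adjusted over the list alone, with NDUFC1 at 0.87 ± 0.17 and NDUFB6 at 0.82 ± 0.18. The list median was 0.67 with a camera adjusted p of 0.00048 (adjusted p = 0.718 with an estimated correlation). Of the 5 late epithelial genes, 4 fell, as did 4 adjusted over the list alone, with KLK10 at -2.46 ± 0.54 and SPRR1B at -2.23 ± 0.57. Their median was -2.23 with an adjusted p of 0.0319 (adjusted p = 0.718 with an estimated correlation). The fibroblast and extracellular matrix list was not called (adjusted p 0.0526), although BGN fell by 1.63 ± 0.11. Of the 10 cytokine and chemokine genes, 2 rose and 5 fell, as many as when adjusted over the list alone, and the list was not called. PTGS2, the inducible cyclooxygenase, fell by 1.59 ± 0.25. Of 3 B cell and plasma cell genes, MS4A1 and CD22 rose, while DERL3, which acts in degradation of misfolded secretory proteins, fell by 0.81 ± 0.10. ZAP70 rose by 0.60 ± 0.12, TRAF1, an adaptor of TNF receptor signalling, rose by 0.83 ± 0.15, and LYZ, the lysozyme gene of macrophages and glands, fell by 2.46 ± 0.46.

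The mean of the muscle list was 0.73 ± 1.43 (SD, n = 12) on the co-infection arrays, above 0 on 8 of them and below 0 on 4. The mean of the stratified epithelium list was -1.33 ± 1.07 and was below 0 on 12 of 12 arrays. With the muscle mean as a covariate, the medians were 0.32 for oxidative phosphorylation and -1.65 for late epithelial genes, and NDUFC1, NDUFB6, KLK10, SPRR1B and IVL passed.

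In co-infection against the pool limma called 1016 genes, with 521 higher and 495 lower, and without centring the split was 602 higher and 432 lower. The larger group gives this comparison a smaller error than the comparisons of 4 arrays, so the counts of the 3 groups do not rank the size of their responses. Between 841 and 1076 genes were called when 1 co-infection array was left out, and 771 genes were called whichever array that was. As in LCV and SIV, each such fit kept the same pool, so these counts leave the pool's own error untested.

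**Figure D2:**
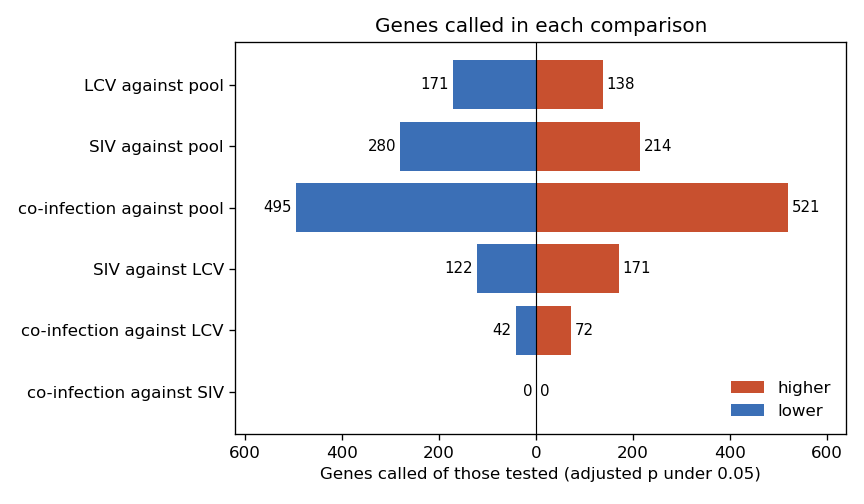
Number of the 2198 tested genes called in each of the 6 comparisons at an adjusted p under 0.05 (x axis), higher to the right and lower to the left. Co-infection against the pool had 1016 calls and co-infection against SIV had 0.

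Between SIV and LCV, where pool and dye cancel, 16 of the 20 genes of the muscle list were higher in SIV and 0 lower. In other lists, 3 of 8 matrix genes and 1 of 7 T cell genes were higher. Of 18 stratified epithelium genes 4 were lower, and of 7 cell cycle genes 1 was lower. The muscle and stratified epithelium lists were written after the data had been seen. NRAP was higher in SIV by 5.75 ± 1.19 (4 against 4 arrays, limma adjusted p = 0.0244), and LDB3, a protein of the muscle Z-disc, by 4.87 ± 1.17. MYF6, a transcription factor of muscle differentiation, was higher by 4.93 ± 1.08. ZAP70 was higher by 1.55 ± 0.30, CCL3 by 2.98 ± 0.69 and IFI27 by 3.63 ± 1.08. DSG3 was lower in SIV (-3.87 ± 1.24), as were CKAP2 (-2.68 ± 0.51) and WEE1, a kinase that holds back entry into mitosis (-2.54 ± 0.73).

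The camera test called 7 lists between SIV and LCV, each at an adjusted p = 0.414 with an estimated correlation. Of the 8 fibroblast and extracellular matrix genes, 3 were higher, both over all genes and adjusted over the list alone, with DCN at 1.85 ± 0.60 and CTSK at 1.82 ± 0.55, a list median of 1.49 and an adjusted p of 0.00812. Of the 7 T cell genes, 1 was higher (2 adjusted over the list alone), with a median of 1.50 and an adjusted p of 0.0195, and CD3G was at 2.63 ± 0.91 with an adjusted p of 0.0563. Without SIV replicate 3 the T cell median was 0.84. Of the 9 interferon-stimulated genes, 1 was higher, as when adjusted over the list alone, with a median of 1.55 and an adjusted p of 0.0374. Of the 5 late epithelial genes, 0 passed over all genes and 5 were lower when adjusted over the list alone, with a median of -3.88, an adjusted p of 0.00915 and SCEL at -4.22 ± 1.42. Of the 7 cell cycle genes, 1 was lower (CDC6, -0.99 ± 0.26) and 5 were lower when adjusted over the list alone, with a median of -0.99 and an adjusted p of 0.00915. Of the 12 oxidative phosphorylation genes, 0 passed over all genes and 2 were higher when adjusted over the list alone, with a median of 0.87 and an adjusted p of 0.00772. Of the 6 lipid and steroid genes, 0 passed over all genes and 5 were lower when adjusted over the list alone, with a median of -1.45 and an adjusted p of 0.00915.

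The muscle and epithelium means differed between SIV and LCV by 3.30 and -2.55. Each of the 2 differences had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays allow, and an adjusted p of 0.0857 over 24 such tests. Both lists hold genes already seen to move, so these p values are not independent evidence. With the muscle mean as a covariate, IFI27 was at 0.44 ± 1.05 and CCL3 at 2.81 ± 0.96. The list medians were then 0.15 for interferon-stimulated genes, 2.93 for T cell genes, 0.71 for matrix genes and -1.52 for late epithelial genes, and the signs of the cell cycle (0.09), oxidative phosphorylation (-0.40) and lipid (0.05) medians turned.

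**Figure D3:**
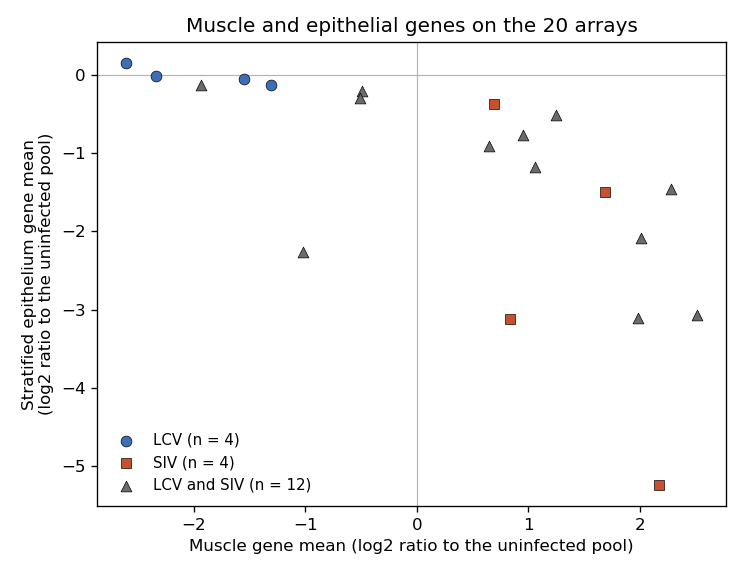
Mean log2 ratio of the muscle list (x axis) and of the stratified epithelium list (y axis) on each of the 20 arrays, with 1 symbol per infection group and lines at the level of the pool. The 4 LCV arrays lie below 0 and the 4 SIV arrays above 0 for muscle, and the 12 co-infection arrays spread from -1.94 to 2.52.

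Between SIV and LCV limma called 293 genes, with 171 higher and 122 lower, and 835 genes had an unadjusted p under 0.05. The count was 71, 10, 4 and 73 without LCV replicates 1, 2, 3 and 4 in turn, 140, 2, 1 and 589 without SIV replicates 1, 2, 3 and 4, and 0 with the muscle mean as a covariate. Called members of the muscle list are part of that mean, so for them the loss is built in. It was 526 with arrays on 1 scale, 491 after quantile normalization, 870 with array weights and 639 with only the SIV and LCV arrays in the fit. The only gene called whichever 1 array was left out was INPP4A, a phosphatase of inositol lipids, at 2.19 ± 0.34 with an adjusted p of 0.00581; it was singled out after its value had been seen. Centring on 6 sets of replicated features in place of all features moved the median of all genes by 1.04, which gave 982 genes higher and 8 lower. Changes are given relative to that shift; on the shifted scale the medians of the other 6 called lists kept their sign, while the cell cycle median (0.05), CDC6 (0.05) and DNAJB11 (0.44, against -0.60 ± 0.20) turned.

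Between co-infection and LCV, 12 of the 20 genes of the muscle list, which was written after the data had been seen, were higher and 0 lower. NRAP was higher in co-infection by 4.98 ± 0.97 (12 against 4 arrays, limma adjusted p = 0.026), LRRC2 by 4.46 ± 0.96 and LDB3 by 4.08 ± 0.95. CYP2F1, a cytochrome P450, was lower (-2.74 ± 0.67), as were IL18, an inflammasome-activated cytokine (-1.87 ± 0.48), and the kinase gene PLK3 (-1.84 ± 0.36). ZAP70 was higher by 1.11 ± 0.25, LYVE1 by 2.63 ± 0.68, EGF by 3.34 ± 0.75 and APOBEC3C, an antiretroviral deaminase, by 1.57 ± 0.41.

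The camera test called 3 lists between co-infection and LCV, each at an adjusted p = 0.477 with an estimated correlation and with 0 members passing over all genes. Of the 12 oxidative phosphorylation genes 7 were higher when adjusted over the list alone, with a median of 0.74 and an adjusted p of 0.0019. Of the 7 cell cycle genes 3 were lower when adjusted over the list alone, with a median of -0.67, an adjusted p of 0.0393 and MCM5 at -0.91 ± 0.31. Of the 6 lipid and steroid genes 0 were lower when adjusted over the list alone, with a median of -0.89 and an adjusted p of 0.0393. With the muscle mean as a covariate the signs of these 3 medians turned, to -0.28, 0.07 and 0.25. The muscle mean differed by 2.68 (exact two-sided permutation p = 0.00275, adjusted p = 0.0659), the epithelium mean by -1.32 (exact p = 0.0231, adjusted p = 0.0857). Both lists hold genes already seen to move, so these p values are not independent evidence.

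Between co-infection and LCV limma called 114 genes, with 72 higher and 42 lower (211 and 209 after quantile normalization), and 709 genes had an unadjusted p under 0.05. The count was 0 without any 1 of LCV replicates 1, 2, 3 or 4, and 0 with the muscle mean as a covariate, which for members of the muscle list is built in. Without co-infection replicates 1 to 12 in turn it was 47, 54, 410, 244, 44, 55, 59, 302, 177, 50, 46 and 70. With arrays on 1 scale it was 441, after quantile normalization 420, with array weights 857 and with only the co-infection and LCV arrays in the fit 60. Centring on the replicated features moved the median of all genes by 0.77, with 641 genes higher and 4 lower, and turned the signs of the cell cycle median (0.08), CDC6 (0.16), DNAJB11 (0.14, against -0.61 ± 0.16) and FDPS (0.38, against -0.38 ± 0.19).

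Between co-infection and SIV no gene passed. INHBA, a subunit of activin, was at -1.49 ± 0.30 (12 against 4 arrays) with an adjusted p of 0.212, the smallest of all, and the B cell receptor gene CD22 was at -1.13 ± 0.33 with an adjusted p of 0.823. On the higher side KRIT1 was at 1.34 ± 0.34 and CKAP2 at 1.35 ± 0.42 (each on 11 against 4 arrays), with adjusted p values of 0.465 and 0.823. The camera test called 3 lists, each at an adjusted p = 0.518 with an estimated correlation and with 0 members passing, over all genes or adjusted over the list alone. Matrix genes had a median of -0.66 (adjusted p 0.000322) with COL3A1, a fibrillar collagen, at -1.75 ± 0.63. T cell genes had a median of -0.53 (adjusted p 0.0128) with CD3G at -1.25 ± 0.75, and late epithelial genes had a median of 1.71 (adjusted p 0.0127) with SPRR1B at 2.31 ± 1.13. The muscle mean differed by -0.62 (exact two-sided permutation p = 0.427) and the epithelium mean by 1.22 (exact two-sided permutation p = 0.138).

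Between co-infection and SIV limma called 0 of 2198 genes, with 101 at an unadjusted p under 0.05 where 110 are expected by chance. The count was also 0 under every alternative tried, among them the other scalings, the array weights, the robust fit, the muscle covariate and the removal of each array, and with 33856 features tested singly. In simulated data with 200 changed genes, 61% of those changed by 1 and 89% of those changed by 2 (log2) were called in this comparison. The simulated genes varied independently, each with 1 spread in all groups. On the real arrays spreads differed (SD of the late epithelial mean 2.82 in SIV, 1.59 in co-infection), so the recovery there is not known. Centring on the replicated features moved the median of all genes by -0.27.

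The 3 responses against the pool were also set side by side. SIV and co-infection shared 179 higher and 251 lower genes, where independence would give 50.7 and 63.1, and 1 gene was called in opposite directions. LCV and co-infection shared 70 higher and 78 lower genes (32.7 and 38.5 under independence) with 9 in opposite directions, and LCV and SIV shared 29 and 49 (13.4 and 21.8) with 8 in opposite directions. Across genes, which are not independent replicates, the log2 ratios correlated at r = 0.856 for SIV and co-infection, 0.274 for LCV and co-infection and -0.0124 for LCV and SIV. A shared pool can give overlap by itself: in simulated unchanged groups whose pool varied like 1 animal the mean r was 0.859, 0.859 and 0.800. The observed covariance of SIV and co-infection was 0.464 against 0.480 in those simulations, and for LCV and SIV it was -0.0078 against 0.479. With a pool that varied like a mean of 4 animals the simulated covariance of SIV and co-infection was 0.120 and the mean r 0.612, so the observed covariance was larger by 0.344, and with a pool error of 0 the simulated mean r was -0.0027. A pool that varied like 1 animal would add the same covariance to all 3 pairs. Both pairs with LCV lay below it, with 0.126 against 0.478 for LCV and co-infection. How many animals the pool held is not given. Whether the overlap of SIV and co-infection exceeds what the shared pool gives depends on that number and on how the true responses relate, neither of which is known.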

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

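The comparison of the replicated features was chosen only after their values had been seen. A search for single arrays far from the others of their group was made by Dixon's ratio in the groups of 4, on 278 gene and list results, and 15 passed where 13.9 are expected by chance. The number of such values therefore is close to what chance gives, and none was left out.

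Among LCV arrays, replicate 2 stood apart for OAS1 (-0.18, the others between -3.24 and -2.78), for the mean of the interferon list (0.0308, the others between -1.97 and -1.67) and for TRAF1 (1.37, the others between 0.26 and 0.35). LCV replicate 3 stood apart for CKAP2 (1.43, the others between 1.95 and 1.99) and for CLEC4E, a receptor of myeloid cells (-0.75, the others between 1.42 and 1.64). APOBEC3G was at -2.44 on LCV replicate 1 (the others between -2.25 and -2.22), and HBG2, a fetal globin gene, was at -0.38 on LCV replicate 4 (the others between -0.05 and 0.01).

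Among SIV arrays, replicate 3 stood apart for ERMAP (3.37, the others between 1.03 and 1.21), IL7R (2.21, the others between 0.85 and 1.07) and SLCO1A2 (-2.98, the others between -4.28 and -4.23). SIV replicate 4 stood apart for MAP1A (-1.05, the others between -0.18 and -0.07), DERL3 (-0.36, the others between -1.29 and -1.17) and CLCA1 (-2.13, the others between -3.16 and -3.13). CKAP2 was at 0.53 on SIV replicate 1 (the others between -1.45 and -1.13), and TICAM2 was at -0.51 on SIV replicate 2 (the others between -0.30 and -0.26).

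A signal also appeared in features that no comparison used. The 6 sets of replicated, unnamed features (244 features) had a mean log2 ratio of 1.56 ± 0.33 (SD) on the 4 LCV arrays and 0.52 ± 0.37 on the 4 SIV arrays, a difference of -1.04 (exact two-sided permutation p = 0.0286, adjusted p = 0.0857 over 24 tests). What these features are is not given in the sources used here. They may be controls added at set ratios, which was not tested; centring the arrays on them gave 990 genes for SIV against LCV, with 982 higher and 8 lower, where centring on all features gave 171 higher and 122 lower.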

How the results depend on the processing

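Chosen only after the data had been seen were the muscle covariate, the replicated-feature centring and the kept zeros, as were the reading of 0 as not measured that all settings but the last share and the muscle list behind the covariate; the other settings were planned. No paired analysis was possible because each array holds a different animal and the replicate numbers pair nothing. For results that did not hold, the cause was not tested unless named. Features at exactly 0 were read as not measured and gave no value except where zeros were kept. Why they were 0 is not known, and array intensities were not used here.

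Leaving out 1 array gave 109 to 143 genes for LCV against the pool (309 with all arrays), 91 to 640 for SIV against the pool (494), 841 to 1076 for co-infection against the pool (1016), 1 to 589 for SIV against LCV (293), 0 to 410 for co-infection against LCV (114) and 0 to 0 for co-infection against SIV. Fewer arrays in groups of 4 lower the counts by construction, but the count of SIV against LCV rose to 589 without SIV replicate 4 and that of co-infection against LCV to 410 without co-infection replicate 3.

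With arrays on 1 scale the counts were 597 for LCV against the pool, 526 for SIV against LCV and 441 for co-infection against LCV, and with quantile normalization they were 542, 491 and 420. Array quality weights gave 984, 870 and 857. With only the arrays of the groups compared they were 839, 639 and 60, and 37 for SIV against the pool. With every feature tested on its own, of 33856 features 4808, 7617 and 14471 were called in LCV, SIV and co-infection against the pool, 4938 in SIV against LCV and 2771 in co-infection against LCV, since more was tested. The muscle covariate gave 111 for SIV against the pool, 0 for SIV against LCV and 0 for co-infection against LCV. The SIV and LCV arrays do not overlap in muscle mean, so its slope comes mostly from the co-infection arrays. Members of the muscle list, among them NRAP, LDB3 and MYF6, are part of the covariate, so their smaller differences are built in. Centring on the replicated features gave 990 for SIV against LCV and 645 for co-infection against LCV, because it moved the median of all genes. The other count settings stayed within 1.5 times the main count.

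Of the 90 list tests, 22 were called. An estimated correlation kept 0 of those 22 calls, and 0 tests were called. Fry kept 13 of them, no centring 22 and array weights 20, and each of these 3 called 26 of the 90 tests. For the shared response, the covariance beyond the simulated one moved for LCV and SIV from -0.487 to -0.00764 with a pool error of 0 and -0.128 with that of a mean of 4 animals. For LCV and co-infection it turned from -0.352 to 0.126 and 0.00700, and for SIV and co-infection from -0.0158 to 0.464 and 0.344.

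Of 4384 values of the 136 named genes under other settings, 3575 kept direction and side of the threshold, 681 lost the call, 110 gained it and 18 turned. CD5 in co-infection against SIV, without 1 array, lay between -0.74 (without SIV replicate 2) and 0.0121 (without SIV replicate 3). With the muscle covariate, SIV against LCV turned for CDC25C (0.0912), TOP2A (0.0897), UQCR11 (-0.20), NDUFB10 (-0.17), COX5A (-0.41) and FZD4 (-0.39), and co-infection against LCV for COL4A4 (-0.49), MCM3 (0.0727), COX5A (-0.21), NDUFB10 (-0.25), LSS (0.24) and FDPS (0.15). With replicated-feature centring, SIV against LCV turned for CDC6 (0.0505) and DNAJB11 (0.44), and co-infection against LCV for CDC6 (0.16), DNAJB11 (0.14) and FDPS (0.38).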

Other observations

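Chosen only after the result was seen were the tests of muscle amount, of a level set by infection status alone, of a single animal and of less epithelium, together with the correlations and the genes with 1 sign on all arrays described here; the tests of infection status, of a single animal and of less epithelium were replaced once the results of their first forms had been seen, the values per array of the muscle, epithelium and gland lists had been seen before any of the tests, and the spread that a value must exceed was set after the first results.

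Of the 2070 genes measured on all 20 arrays, 51 were below the pool and 32 above it on every array. The lower ones include the secreted gland genes SMR3A (-6.25 ± 3.04, SD, n = 20), LACRT (-4.27 ± 1.26) and PIP (-2.88 ± 1.75), and the steroid enzyme HSD17B3 (-2.50 ± 0.50). The higher ones include the transcription factor SOX6 (0.97 ± 0.48) and ST6GAL1, a sialic acid transferase (0.85 ± 0.39). The mean of the added gland list was -2.02, -2.16 and -2.02 in LCV, SIV and co-infection, and its differences between groups had exact two-sided permutation p values of 0.800, 0.991 and 0.841. Since all arrays share 1 pool and 1 dye order, such values belong as much to the pool as to infection.

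Within the 12 co-infection arrays, animals with higher muscle genes had lower epithelial genes. The muscle mean and the stratified epithelium mean correlated at r = -0.603 (permutation p = 0.0401, adjusted p = 0.0801 over 4 relations) and rho = -0.629 (permutation p = 0.0330, adjusted p = 0.0659), with r = -0.822 without the 2 arrays farthest from the muscle median. Muscle and T cell means correlated at r = -0.620 (permutation p = 0.0298, adjusted p = 0.0801) and rho = -0.657 (permutation p = 0.0241, adjusted p = 0.0659), with r = -0.430 without those 2 arrays. For the late epithelial mean r was -0.465 (permutation p = 0.127, adjusted p = 0.170) and rho -0.559 (permutation p = 0.0622, adjusted p = 0.0830), and for the gland mean r was -0.180 (permutation p = 0.572, adjusted p = 0.572) and rho -0.392 (permutation p = 0.212, adjusted p = 0.212). None of the 4 relations passed the adjustment.

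Muscle genes were higher in SIV and co-infection than in LCV. A difference in array scale is argued against by the signs of the list's median against the pool, -2.01 in LCV and 1.43 in SIV, since scaling keeps signs. With every array on 1 scale the median difference was 3.62 (3.43 otherwise). For the same reason scaling could hardly have removed it, so that value adds little. Different amounts of skeletal muscle in the tissue samples may account for the pattern: 12 muscle genes that the naming rule had not picked had a median correlation of 0.9 between any 2 over the co-infection arrays, where 1000 random lists of that size had a median of -0.0129 and a highest value of 0.435. That set of 12 was defined after the correlation of the whole list had been seen. A level set by infection status alone is argued against by the 12 co-infection arrays, all of 1 status, whose muscle mean ran from -1.94 to 2.52. That span of 4.46 takes in all SIV arrays (0.69 to 2.18) and reaches into the LCV range (-2.61 to -1.31). A test by sets of 4 co-infection arrays decided nothing, with a median range of 3.02 where the SIV and LCV means differed by 3.30. Sampling depth and a partial effect of infection on the tissue cannot be told apart and stay open.

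The late epithelial list was lower in SIV than in LCV, with a median difference of -3.88, but 0 of its 5 genes passed over all genes and its camera call was lost with an estimated correlation (adjusted p = 0.414). Muscle taking the place of epithelium and a true fall of these genes cannot be told apart, because with the muscle mean as a covariate the median was -1.52, and the difference of the list's mean per array was -1.54 with an SE of 1.57 (-3.59 without the covariate). Without SIV replicate 3, the lowest array, the median difference was -2.67 (median SE 1.30), so its direction did not rest on that array alone. The SD of the list mean over the 4 SIV arrays was 2.82, so dependence on few animals stays open. The 3 SIV arrays left had a median list mean of -2.33, the value of 1 array, where the LCV mean was -0.06 ± 0.30 (SD). Of those 3 arrays 2 lay more than 3 SD below the LCV mean, while SIV replicate 4, at -0.51, was near the lowest LCV array (-0.31). An effect of SIV on the epithelium stays open.

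The T cell list was higher in SIV than in LCV, with a median difference of 1.50, but 1 of its 7 genes passed, its camera call was lost with an estimated correlation (adjusted p = 0.414), and its mean per array had an exact two-sided permutation p of 0.0571 (adjusted p = 0.137). With the muscle mean as a covariate the median was 2.93, although no single T cell gene passed. The difference of the list's mean per array was then 2.14 with an SE of 0.75 (1.29 without the covariate). These values rest on a slope mostly from the co-infection arrays, where muscle and T cell means correlated at r = -0.620, or -0.430 without 2 arrays. SIV and LCV arrays do not overlap in muscle mean. Muscle content as the cause is therefore argued against only if that slope holds between the groups. Less epithelium as the whole cause would raise the markers of every other cell type alike. Muscle and gland genes moved apart. The mean of the 12 muscle genes minus the gland mean differed by 2.50 with an SE of 0.48 (exact two-sided permutation p = 0.0286). The values of both lists had been seen before this test was chosen, so it does not count against that cause. The T cell mean minus the gland mean differed by 1.42 with an exact two-sided permutation p of 0.171, so less epithelium stays open. A larger share of T cells in SIV stays open, and without SIV replicate 3 the median was 0.84.

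Other splits of the arrays were fitted for each comparison between infected groups. For SIV against LCV, 1 of the 35 splits, the real one, called as many as 293 genes, and the highest other called 1. Among 35 splits no better rank is possible, and the count fell to 1 without SIV replicate 3. Chance is therefore less likely for that count but not excluded. For co-infection against LCV, 2 of 100 splits, the real one included, called at least the real 114 genes, a share under 0.05. The highest other split called 352, and the real count fell to 0 without any 1 LCV array, so chance cannot be excluded for that count. What the split with 352 calls separated was not examined. For co-infection against SIV the real count was 0, which 100 of 100 splits reach by construction, so the count decides nothing about chance. Of these splits 12 called any gene, the highest 588, and what they separated was not examined.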
